A study of Mus musculus with 18 samples.

How the data were processed

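The series profiles naive CD4 T cells from C57BL/6 mice, sorted by flow cytometry as CD4-positive, CD25-negative cells with a naive surface phenotype. Some single genes are not reported here. The mice belonged to 6 genotypes with 3 libraries each, 18 libraries in all. Wild-type mice (WT) served as the common control. Cluster Tg mice over-expressed the whole miR-232724 microRNA cluster in T cells. The miR-23 Tg, miR-24 Tg and miR-27 Tg mice over-expressed a single family member in T cells. DKO mice lacked both copies of the cluster, a and b, in T cells. Per the labels, total RNA that kept the small RNAs was prepared with a miRNeasy kit, libraries were made with an Illumina TruSeq RNA kit and sequenced on an Illumina HiSeq. The labels say that the cells came from mice of each genotype but not that every library came from a separate animal, so p-values measure the spread between these libraries, part of which may be technical.

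The authors deposited 1 table of RPKM values (read counts scaled to transcript length and library size) with 23953 gene rows and 18 library columns. Per the submitters' processing notes, STAR 2.2.0c, HOMER and the mouse build mm9 were used; the role of each tool, the gene models, the counting of reads shared between genes and the use of strand are not given in the sources used here. Values of genes that share reads with a paralog, a pseudogene or an overlapping gene are therefore uncertain, which applies to the hairpins of the cluster and to the haemoglobin, histone and H2 class II genes. The values hold no read counts, and 75 gene rows held a value above 0 far smaller than any read could give, so an entry at 0 is described only as listed at 0. In the header, 2 of the 3 columns of miR-23 Tg carry the same replicate name. These 2 columns were used as members of the genotype without a replicate number, and are called miR-23 Tg columns 3 and 4. They were the closest pair of libraries (r = 0.994), with 0 identical values among 10119 genes at 1 RPKM or more in both. That they hold separate samples is assumed where n = 3 is given for miR-23 Tg. Of the gene symbols, 27 had been turned into calendar dates, and 2 rows repeated a symbol; of repeated symbols the row with the highest mean was used.

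Relative depth was estimated from genes below 0.1 RPKM, whose values are small multiples of the value of a single read. It ranged from 0.634 in miR-27 Tg replicate 3 to 1.47 in cluster Tg replicate 3, relative to WT replicate 1. The WT libraries lay between 0.912 and 1.13, and the 3 cluster Tg libraries all lay above them, the lowest at 1.299. Absolute depth is unknown, and no counting interval is given. Over all tested genes the median standard error of a comparison of 3 libraries with 3 was 0.20 on the log2 scale.

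Tests were run on log2(RPKM + 1), and every fold change is on the log2(RPKM + 1) scale, which understates the change of genes with low values. Genes with at least 1 RPKM in at least 3 of the 18 libraries were kept, 11099 in all. The moderated test of limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) was fitted to all 18 libraries with the genotype as the only term, so that all comparisons share the spread per gene. The comparisons were each of the 5 other genotypes with WT, cluster Tg with DKO, an F test over the 6 genotypes, and the change in cluster Tg against the sum of the changes in the 3 single transgenics. A gene is called where the Benjamini-Hochberg adjusted p was under 0.05. Data were simulated for 11099 independent genes at the spread per gene pooled over all 18 libraries, with changes put into cluster Tg. Against WT, the test recovered 57% of 100 genes changed by a log2 of 1 and 8% of 100 genes changed by 0.5. It made 1 false call among the genes left unchanged. The smallest p of an exact permutation test of 3 libraries against 3 is 0.1.

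There were 30 gene lists. They cover naive and quiescence genes, T cell receptor (TCR) and immediate early response, effector and memory T cells, Th1, Th2, Th17, Treg and Tfh cells, TGF-beta signalling, type I interferon response, cell cycle, apoptosis, glycolysis, cholesterol biosynthesis, ribosomal proteins, cytokine receptors and JAK-STAT, the TCR complex with proximal signalling, and literature targets of miR-23, miR-24 and miR-27. Further lists hold markers of B cells, CD8 T cells, NK cells, myeloid cells, neutrophils, dendritic cells, erythroid cells and thymocytes, a dissociation and heat stress list, and replication-dependent histones. Lists share members, for example Cxcr3 and Tbx21 in the effector and Th1 lists and Cd8a in the CD8 and thymocyte lists. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Of 66 list calls at the preset correlation, with those of the sum left out, 3 held with the estimated one: the interferon list in DKO vs WT, and the effector and Treg lists in cluster Tg vs DKO.

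MicroRNA target sites were sought in the longest annotated 3′ UTR per symbol, from GENCODE M21 on GRCm38, since no annotation of mm9 was at hand; no coordinates are given. Of the symbols, 22635 matched an annotated gene directly and 894 through a synonym, and 20371 had a 3′ UTR. A site is a match to the seed of the microRNA (AATGTGA for miR-23, CTGAGCC for miR-24, ACTGTGA for miR-27). Across 10233 genes, the log2 fold change was regressed on the presence of a site, with UTR length and GC share as further terms. The t value of the site was ranked among those of 15410 other 7-base words, and the share of words as extreme gave a p (one-sided: lower in a transgenic, higher in DKO), adjusted over 9 tests. Genes are not independent replicates, so the mean level of site genes minus length-matched genes was also compared library by library with an exact permutation test. On simulated data with a shift of -0.1 put in, the regression found -0.10 for miR-23 and miR-27 and -0.0955 for miR-24. Comparisons with WT share 3 control libraries. Overlaps of their calls are therefore given beside the value for independent lists and beside simulations of unchanged groups, and part of an excess may come from the shared controls, since 3 libraries cannot be split into 2 groups of 2.

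The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named per comparison with WT were the 10 genes with the largest rise and the 10 with the largest fall among called genes whose libraries all lay on one side of WT, with a mean of at least 2 RPKM in either group, passing over clone-style and microRNA symbols. In cluster Tg 516 higher and 275 lower genes were eligible, and 37 higher and 17 lower ones were passed over for their names. If no gene passed, the 5 with the smallest p were taken. Further named genes were up to 4 members of each list with a call, the hairpins and host gene of the cluster, the 5 site genes with the largest fall per family, up to 10 genes called in opposite directions in cluster Tg and DKO (there were 0), and the literature targets. Alternatives changed the pseudocount to 0.1, dropped the filter or the variance trend, normalised by quantiles or median ratios, blocked on the replicate number, left out each library of the groups compared, fitted only the 6 libraries compared, kept all rows, and varied the site definition. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the site tests, simulations of sites and figures.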

Results

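RNA was profiled in naive CD4 T cells of 6 mouse genotypes, with 3 libraries each, to compare gain and loss of the miR-232724 microRNAs. The cluster is transcribed as a single precursor that carries miR-23, miR-27 and miR-24, microRNAs that lower the level of mRNAs with matching sites in their 3′ UTRs. Between 10104 and 10616 genes per library reached 1 RPKM. Values are mean RPKM ± SD over n = 3 libraries per genotype, fold changes are log2 values on the log2(RPKM + 1) scale, and adjusted p-values are from limma. The libraries miR-27 Tg replicate 3 and DKO replicate 3 stood apart from the other 16. Their scores on the first principal component, which held 24.8% of the variance, were 122.5 and 51.3, while the others lay between -20.8 and -0.320. The second component (14.7%) separated WT, DKO and miR-23 Tg libraries (16.4 to 30.2) from those of cluster Tg, miR-24 Tg and miR-27 Tg (-43.95 to -6.61), and whether these sets were prepared separately is not given in the sources used here. The mean RPKM of ribosomal protein genes was 2486 and 1677 in these 2 libraries and 436.5 to 968.8 in the others. Transcripts of the sex chromosomes were mixed within the genotypes except miR-23 Tg, whose 3 libraries all had Xist, at 45.8 to 59.1 RPKM, and Ddx3y of at most 0.0268. Cluster Tg replicate 2 had both Xist, at 45.8, and the Y-linked Ddx3y, at 20.1.

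The hairpins of the targeted locus stood far above WT in the transgenics labelled for them. Mir23a stood at 91296 ± 75374 RPKM in cluster Tg and 69164 ± 5106 in miR-23 Tg, against 0 to 279.5 over the WT libraries, with a mean of 120.8. Mir27a stood at 91741 ± 71575 in cluster Tg and 159890 ± 114598 in miR-27 Tg, against 140.0 ± 49.7 in WT. Mir24-2 stood at 38044 ± 28519 in cluster Tg and 28270 ± 18571 in miR-24 Tg, against 33.1 ± 13.6 in WT. Against WT, limma called all of these, with adjusted p from 0.000388 for Mir27a in miR-27 Tg to 0.0140 for Mir23a in cluster Tg, except Mir23a in miR-23 Tg. There the log2 fold change of 11.23 (SE 2.60) had an adjusted p = 0.184. In miR-27 Tg replicate 3, Mir27a was 27980.5, below the 216755 and 234933 of the other libraries of that genotype. In DKO, Mir24-2 was listed at 0 in all 3 libraries, as it also was in 1 library each of miR-23 Tg and miR-27 Tg. Mir27a ranged from 0 to 39.5 in DKO, below the 95.6 of the lowest WT library, and Mir23a from 0 to 76.1, within the WT range, so Mir23a did not separate DKO from WT. The hairpins of the second cluster (Mir23b, Mir27b and Mir24-1) were listed at 0 in all 18 libraries, so its deletion could not be checked. Its host gene 2010111I01Rik is not one of the microRNAs, and its level checks nothing. It was 25.1 ± 6.50 in WT and 46.4 ± 8.05 in DKO (adjusted p = 1.00). It rose to 53.7 ± 6.58 in cluster Tg (adjusted p = 0.0243) and to 72.02 ± 39.8 in miR-27 Tg (adjusted p = 0.00662). The 3 hairpins took 42.6%, 20.8% and 13.3% of the RPKM sum in the cluster Tg libraries, and 0.0198% to 0.0708% in those of WT.

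**Figure D1:**
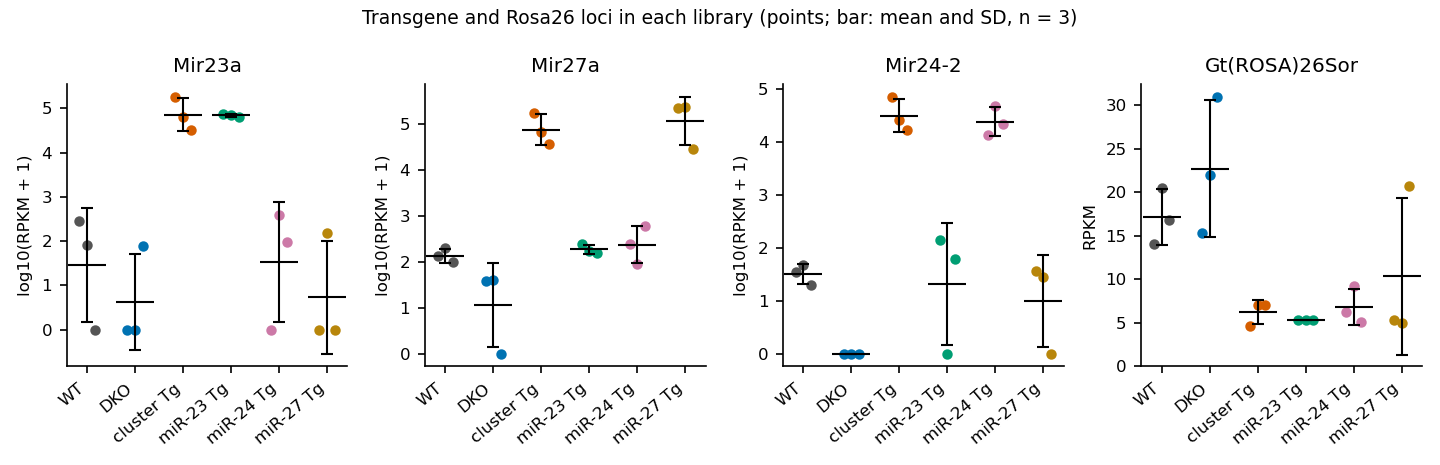
Level of Mir23a, Mir27a and Mir24-2 as log10(RPKM + 1), and of Gt(ROSA)26Sor in RPKM, in each library (points), with the mean and SD of n = 3 per genotype. The hairpins lie far above WT in cluster Tg and in the transgenic of the same name, and Mir24-2 is listed at 0 in the 3 DKO libraries.

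Over-expression of the whole cluster was compared with WT to ask which transcripts move with all 3 microRNAs. Tmem176b and its neighbour Tmem176a, which encode membrane proteins, stood at 70.8 ± 28.3 and 45.0 ± 19.5 RPKM against 3.81 ± 1.44 and 2.17 ± 0.380 in WT. The granzyme Gzmk stood at 14.5 ± 5.64 against 0.249 ± 0.05, the memory surface antigen Ly6c2 at 62.0 ± 35.0 against 4.02 ± 0.597, and the chemokine receptor Cxcr3 at 22.9 ± 7.54 against 1.45 ± 0.489. Calcium-binding S100a4 and S100a6, the co-receptor Nrp1 and the chemokine Ccl5 rose by log2 values of 3.36, 3.58, 3.28 and 3.18. Falls included Rgs11, a regulator of G protein signalling (3.18 ± 1.02 against 16.2 ± 3.61), and Slc16a5, a monocarboxylate transporter (5.08 ± 1.45 against 22.9 ± 3.38). The protease inhibitor Slpi (0.297 ± 0.227 against 4.61 ± 0.805) and the small GTPase Rhob (2.92 ± 0.638 against 15.7 ± 4.19) fell too. In all, limma called 941 of 11099 genes, 625 higher and 316 lower, and 307 of them changed by a log2 of 1 or more. With quantile normalisation, which evens out the direction, 564 were higher and 611 lower.

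Of 32 measured effector and memory genes in cluster Tg, 22 rose, 1 fell and the rest were not called (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.39. Camera called the list at adjusted p = 1.72e-19, while the adjusted p = 0.0763 with an estimated correlation. The membrane-binding Anxa2 stood at 69.1 ± 13.5 against 9.10 ± 2.32, and the member that fell was Fasl, the death ligand of killing T cells (log2 -0.78, adjusted p = 0.00656). Of 14 Th1 genes, 6 rose (8 higher and 1 lower adjusted over the list alone), among them the master regulator Tbx21 (3.44 ± 1.35 against 0.320 ± 0.0267) and Il18rap. Camera gave an adjusted p = 2.22e-05, and the adjusted p = 0.1 with an estimated correlation. Of 14 Tfh genes, 7 rose (10 adjusted over the list alone), with the cytokine Il21 at 1.97 ± 0.133 against 0.179 ± 0.101, and the inhibitory receptor Pdcd1 at 15.2 ± 1.99 against 2.9 ± 0.0792. The co-stimulator Icos and the repressor Bcl6 rose by log2 values of 1.01 and 0.86 (camera adjusted p = 7.09e-08 for the list, adjusted p = 0.0763 with an estimated correlation). Of 17 Treg genes, 4 rose (7 adjusted over the list alone): Nrp1, the ectoenzymes Entpd1 and Nt5e, and the transcription factor Ikzf2 (camera adjusted p = 1.96e-06, adjusted p = 0.0763 with an estimated correlation). Th17 genes had 2 rises of 11, Il21 and Rora (4 adjusted over the list alone; camera adjusted p = 0.00798, adjusted p = 0.474 with an estimated correlation).

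Of 30 interferon-stimulated genes in cluster Tg, 17 rose and none fell (22 adjusted over the list alone), with a median of 0.96. The antiviral Ifit1 stood at 44.7 ± 4.35 against 14.1 ± 2.59, Ifit3 at 34.9 ± 6.85 against 9.04 ± 2.39, and the oligoadenylate synthetases Oas1a and Oasl2 both rose by 1.63. Camera gave an adjusted p = 1.14e-14, and the adjusted p = 0.1 with an estimated correlation. Of 32 cell cycle genes, 4 rose and 1 fell (11 and 1 adjusted over the list alone), the rises being the helicase Mcm7, the nucleotide enzymes Rrm2 and Tk1 and the cyclin Ccnb2, and the fall the helicase Mcm2. Camera gave an adjusted p = 0.000712, and the adjusted p = 0.602 with an estimated correlation. The calls of Ccnb2 and Tk1 were lost under quantile normalisation. Apoptosis genes moved both ways (30 measured, 3 and 2 adjusted over the list alone), with Pmaip1 among 3 that rose, and Bid (6.80 ± 0.231 against 12.5 ± 0.748) and Fasl the 2 that fell.

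Markers of other cells also rose in cluster Tg, as measured in the same libraries as the effector and interferon genes. Of 7 CD8 T cell markers, Cd8a (7.17 ± 3.98 against 0.394 ± 0.165), Nkg7 and Eomes rose and Ctsw fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.00470, adjusted p = 0.201 with an estimated correlation). Of 6 measured thymocyte genes, 3 rose: Cd8a, Ikzf2 and the terminal transferase Dntt at 20.4 ± 3.89 against 6.90 ± 0.895 (4 adjusted over the list alone; camera adjusted p = 4.20e-05, adjusted p = 0.0763 with an estimated correlation). Of 14 B cell markers, only the class II chain H2-Aa was called (20.9 ± 9.23 against 3.72 ± 1.66), with 11 adjusted over the list alone and a median of 1.26 (camera adjusted p = 4.24e-06, adjusted p = 0.474 with an estimated correlation). The myeloid markers Itgam and Ccr2 rose, 2 of 6 (2 adjusted over the list alone; camera adjusted p = 0.0148, adjusted p = 0.177 with an estimated correlation).

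Few genes of the naive state were called in cluster Tg. Of 24, 2 rose, among them S1pr1, a receptor for egress from lymphoid organs, and Igfbp4, a binding protein of insulin-like growth factors, fell (272.0 ± 42.1 against 688.0 ± 213.4) and 21 were not called (2 higher and 1 lower adjusted over the list alone). Quantile normalisation ended both calls of rises (adjusted p = 0.0533 for S1pr1). Ribosomal protein genes had a median of -0.75 with 0 of 40 called by limma (0 adjusted over the list alone), at a camera adjusted p = 1.18e-07 and an adjusted p = 0.624 with an estimated correlation. The heat stress list had 1 fall of 15, the chaperonin Hspd1 (camera adjusted p = 0.0428, adjusted p = 0.813 with an estimated correlation), a call that was lost under quantile and median-ratio scaling, and without WT replicate 1, WT replicate 2 (adjusted p = 0.0750) or cluster Tg replicate 3, list tests chosen after seeing the data. The other list calls in cluster Tg held with each of the 6 libraries left out. Camera did not call the remaining lists. Of these, the members that rose, fell and were measured numbered 5, 0 and 33 for cytokine receptors (Il10ra at 32.9 ± 6.08 against 11.6 ± 1.85). They numbered 2, 0 and 12 for Th2 (Maf and Il17rb), 2, 0 and 18 for glycolysis (Aldoc and Pgam1) and 1, 0 and 30 for the TCR response (Egr2). No member was called for the TCR complex (35 measured), TGF-beta signalling (16), cholesterol biosynthesis (20), NK (5), neutrophil (5), erythroid (5) or histone genes (5). Median and mean differed in sign for the TCR complex, histone, apoptosis and miR-23 target lists, and the neutrophil list had a positive median and mean with a test direction downwards. Dendritic markers, 3 of 9 measured, were too few to test. Leaving out cluster Tg replicate 1 or WT replicate 1, 2 or 3 moved the 941 calls to 419, 570, 623 or 568. There were 3225 calls without miR-27 Tg replicate 3 and DKO replicate 3, an alternative chosen after seeing the data, where the Th17, myeloid and heat stress calls were lost, and 2302 in a fit of only the 6 libraries.

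**Figure D2:**
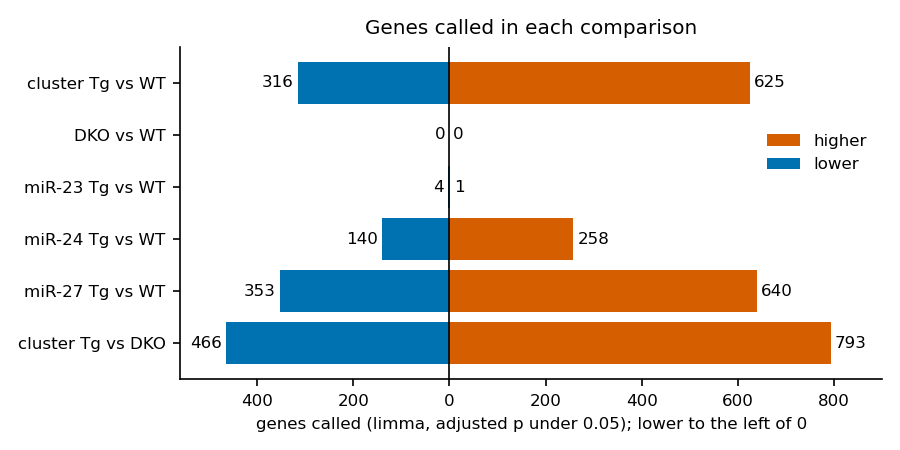
Number of genes called higher (right of 0) and lower (left of 0) by limma in each comparison. Cluster Tg and miR-27 Tg had 941 and 993 calls against WT, miR-24 Tg had 398, miR-23 Tg had 5 and DKO had 0.

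Over-expression of miR-24 alone was compared with WT in the same way. Ccl5 stood at 35.1 ± 15.4 RPKM against 1.93 ± 1.5 in WT, Cxcr3 at 16.4 ± 8.55 against 1.45 ± 0.489, the gut homing receptor Ccr9 at 24.2 ± 5.73 against 2.45 ± 0.689, and the actin regulator Coro2a at 49.1 ± 8.73 against 5.86 ± 6.30. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 and the invariant chain Cd74 rose by log2 values of 3.28, 3.01, 2.91 and 2.75, with wide spreads (Cd74 at 123.5 ± 92.7 against 14.98 ± 4.05). Falls included Igsf23 (5.12 ± 0.761 against 27.8 ± 7.19), Igfbp4 (172.6 ± 26.4 against 688.0 ± 213.4), Slc16a5, Rgs11 and Ttyh3, a chloride channel (25.5 ± 4.47 against 84.8 ± 4.44). The tetraspanin Cd81, the creatine kinase Ckb and the protease Adamts14 fell by log2 values from -1.58 to -1.43. Limma called 398 genes, 258 higher and 140 lower (219 and 199 with quantile normalisation), 144 of them with a log2 change of 1 or more.

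Of 32 effector and memory genes in miR-24 Tg, 14 rose (25 adjusted over the list alone), with a median of 1.18 and Anxa2 at 49.96 ± 8.001 against 9.10 ± 2.32. Camera gave an adjusted p = 7.01e-23, and the adjusted p = 0.0577 with an estimated correlation. In the same libraries 9 of 14 B cell markers rose (13 adjusted over the list alone; median 1.86; camera adjusted p = 3.17e-14, adjusted p = 0.126 with an estimated correlation), including the co-receptor Cd22 (4.81 ± 3.23 against 0.390 ± 0.133) and the adaptor Bank1. Of 14 Th1 genes, 7 rose, with Il18r1, a receptor subunit for interleukin-18, at 87.4 ± 6.83 against 29.4 ± 5.21, and Tbx21 at a log2 of 1.63 (8 adjusted over the list alone; camera adjusted p = 1.02e-07, adjusted p = 0.0606 with an estimated correlation). Of 17 Treg genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with Nrp1 at 13.3 ± 3.91 against 2.15 ± 0.205, and the lineage factor Foxp3 at 8.76 ± 6.26 against 2.71 ± 0.212. Cd83, Nt5e and Il2ra were the other rises and the receptor Gpr83 the fall (camera adjusted p = 2.33e-06, adjusted p = 0.0606 with an estimated correlation). Quantile normalisation ended the calls of Foxp3 (adjusted p = 0.0544) and Il2ra (adjusted p = 0.0747). Tfh genes had 3 rises of 14, Pdcd1, Il21 and Bcl6 (5 adjusted over the list alone; camera adjusted p = 3.48e-05, adjusted p = 0.126 with an estimated correlation).

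Other lineage markers moved in miR-24 Tg as well. The NK receptors Klrd1 (38.9 ± 3.41 against 11.5 ± 2.68) and Klrk1 rose, 2 of 5 (4 adjusted over the list alone; camera adjusted p = 2.53e-06, adjusted p = 0.0659 with an estimated correlation). Cd8a (3.99 ± 0.992 against 0.394 ± 0.165) and Nkg7 were the 2 of 7 CD8 markers that rose (4 adjusted over the list alone; camera adjusted p = 0.00213, adjusted p = 0.126 with an estimated correlation), and Cd8a and Dntt the 2 of 6 thymocyte genes (4 adjusted over the list alone; camera adjusted p = 0.000218, adjusted p = 0.0745 with an estimated correlation). No myeloid or neutrophil marker was called, although 5 of 6 and 3 of 5 passed when adjusted over the list alone (camera adjusted p = 0.00278 and 0.00867, adjusted p = 0.0880 and 0.406 with an estimated correlation). Lyz2 was 7.01 ± 7.53 against 0.431 ± 0.422, and S100a8, listed at 0 in WT, was 20.2 ± 23.2. Of 35 genes of the TCR complex, the receptor regulator Cd5 fell (166.8 ± 1.76 against 257.4 ± 21.6) and the rest were not called, with a median of -0.13 (2 lower adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.342 with an estimated correlation). Quantile normalisation ended both the call of Cd5 (adjusted p = 0.0596) and that of the list. Camera also called Th17 genes (1 of 11 rose, Il21; 4 adjusted over the list alone; adjusted p = 0.0363, adjusted p = 0.466 with an estimated correlation), cholesterol genes (0 of 20 called; adjusted p = 0.0290, adjusted p = 0.462 with an estimated correlation) and, downwards, ribosomal protein genes (0 of 40; adjusted p = 0.00242, adjusted p = 0.683 with an estimated correlation). The interferon list, with 0 of 30 called and a median of 0.13, was not called (camera adjusted p = 0.407). Among members of lists without a camera call or outside those above, Il10ra, Il18r1, Stat4 and Il2ra rose, as did the proapoptotic Pmaip1 and the transcription factor Maf, while the hexokinase Hk1 and the replication factor Mcm2 fell. Quantile normalisation ended the calls of Pmaip1 (adjusted p = 0.0612) and Hk1 (adjusted p = 0.131). Leaving out miR-24 Tg replicate 1 or 3, or WT replicate 1, 2 or 3, moved the 398 calls to 180, 242, 181, 202 or 191. Of the list calls, the neutrophil one was lost without miR-24 Tg replicate 1 (median 1.05, adjusted p = 0.102), the Th17 one without WT replicate 3 (adjusted p = 0.0958), and the cholesterol one without miR-24 Tg replicate 1 or 2, WT replicate 1 or WT replicate 3 (adjusted p = 0.166). There were 1937 calls without the 2 libraries that stood apart, where the Th17 call was lost, and 851 in a fit of the 6 libraries alone.

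Over-expression of miR-27 alone gave 993 calls against WT at the spread shared by all genotypes, of which 640 were higher and 353 lower (544 and 423 with quantile normalisation). A fit of the 6 libraries compared gave 43. Tmem176b stood at 82.5 ± 49.4 RPKM against 3.81 ± 1.44, the antibody joining chain Igj at 17.6 ± 9.22 against 0.121 ± 0.0480, Cd74 at 281.7 ± 234.4 against 14.98 ± 4.05, and the myeloid protein S100a9 at 101.9 ± 155.4 against 0.0462 ± 0.0801. H2-Ab1, H2-Aa, H2-Eb1 and Plac8 rose by log2 values of 3.89, 3.80, 3.76 and 3.64, and S100a8, listed at 0 in WT, was 99.7 ± 159.3. The protease Ctsw (14.5 ± 7.90 against 57.9 ± 7.26) and the pore-forming Prf1 (3.21 ± 1.35 against 14.6 ± 1.91) fell. The tetraspanin Tspan9 (1.08 ± 0.199 against 8.90 ± 3.34), the G protein regulator Rgs1, the GTPase Rhob and Pdk1, a kinase that holds back pyruvate oxidation (33.2 ± 6.68 against 96.1 ± 2.68), also fell. Snord88a, a small nucleolar RNA, was listed at 0 in all 3 miR-27 Tg libraries and was 186.4 ± 109.8 in WT. Of the calls, 325 changed by a log2 of 1 or more.

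Of 30 interferon-stimulated genes in miR-27 Tg, 22 rose and none fell (28 adjusted over the list alone), with a median of 1.13. Ifit1 stood at 69.1 ± 7.43 against 14.1 ± 2.59, Oas1a at 22.8 ± 7.52 against 3.88 ± 0.185, Oas2 at 98.8 ± 32.6 against 26.7 ± 1.89, and Ifit3 rose by a log2 of 2.40. Camera gave an adjusted p = 5.42e-17, and the adjusted p = 0.161 with an estimated correlation. All 14 measured B cell markers rose in the same libraries (14 adjusted over the list alone; median 2.45; camera adjusted p = 6.36e-13, adjusted p = 0.247 with an estimated correlation), with the receptor component Cd79a at 14.7 ± 7.66 against 1.23 ± 0.213. Myeloid markers had 5 rises of 6, among them Lyz2 (13.1 ± 8.19 against 0.431 ± 0.422), Itgam, Tyrobp and Fcer1g (5 adjusted over the list alone; camera adjusted p = 0.000587, adjusted p = 0.161 with an estimated correlation). Neutrophil markers had 2 of 5 called, S100a8 and S100a9 (5 adjusted over the list alone; camera adjusted p = 0.00297, adjusted p = 0.353 with an estimated correlation).

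Of 32 effector and memory genes in miR-27 Tg, 15 rose and 2 fell (21 and 2 adjusted over the list alone), with a median of 1.15. Camera gave an adjusted p = 1.22e-08, and the adjusted p = 0.247 with an estimated correlation. Gzmk (4.92 ± 1.59 against 0.249 ± 0.05) and Anxa2 were among the rises, and Prf1 and Fasl (2.64 ± 0.755 against 6.55 ± 0.555) were the falls. Of 32 cell cycle genes, 10 rose and none fell (18 adjusted over the list alone; median 0.62), with Ccnb2 at 6.54 ± 2.30 against 1.89 ± 1.13, Rrm2 at 10.1 ± 1.15 against 3.92 ± 2.54, Tk1 and the thymidylate synthase Tyms (camera adjusted p = 1.00e-06, adjusted p = 0.331 with an estimated correlation). Apoptosis genes had 1 rise and 3 falls of 30 (2 and 5 adjusted over the list alone). The survival factor Bcl2l1 rose, and Bid (5.61 ± 0.231 against 12.5 ± 0.748), Fasl and Bik fell. CD8 markers had 3 rises of 7, among them Cd8a, Nkg7 and Cd8b1, and 1 fall, Ctsw (4 and 1 adjusted over the list alone; camera adjusted p = 0.0229, adjusted p = 0.331 with an estimated correlation). Treg, Tfh, NK and thymocyte genes had 4 of 17, 3 of 14, 2 of 5 and 2 of 6 rises (7, 8, 4 and 3 adjusted over the list alone; camera adjusted p = 0.00297, 0.0186, 0.0229 and 0.0341). With an estimated correlation the adjusted p was 0.247, 0.377, 0.353 and 0.331.

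Camera further called TGF-beta signalling lower in miR-27 Tg (1 of 16 fell, the signal transducer Smad2 at 6.78 ± 1.41 against 9.69 ± 0.396; 1 adjusted over the list alone; adjusted p = 0.0414, adjusted p = 0.573 with an estimated correlation) and erythroid genes higher (0 of 5 called, 3 adjusted over the list alone; adjusted p = 0.0447, adjusted p = 0.413 with an estimated correlation). Among single members of lists without a call, Il10ra (32.9 ± 4.59 against 11.6 ± 1.85), Stat2, Ifnar2, Socs1, Tbx21, Cxcr3, Maf, Aldoc, Fdft1 and Slfn2 rose, and Il6st, Ccr8, Myc and Cblb fell. Cd5, which fell in miR-24 Tg, was 375.1 ± 50.2 against 257.4 ± 21.6 in miR-27 Tg (log2 0.54, adjusted p = 0.0123), a call lost with quantile normalisation (adjusted p = 0.122), as were those of Bcl2l1, Fdft1, Ifnar2 and Socs1. Leaving out WT replicate 1, 2 or 3 moved the 993 calls to 533, 613 or 548. Leaving out both libraries that stood apart gave 2218, of which 924 were among the 993, and a fit of the 6 libraries alone gave 43. The SD of log2 ratios was 1.12 and 1.145 for miR-27 Tg replicate 3 against its genotype, and 0.291 to 0.336 between WT libraries. With replicate 3 included, the spread shared by all comparisons was thus likely too narrow for this one. Without the 2 libraries the CD8, NK, neutrophil, erythroid and TGF-beta lists were no longer called, nor were Snord88a (adjusted p = 0.0513), Rhob (adjusted p = 0.0618), Fdft1, Socs1 and Ccr8. With single libraries left out, the Tfh and thymocyte calls were lost without miR-27 Tg replicate 1 (adjusted p = 0.154 and 0.216) or 2, and the CD8 call without replicate 1 (adjusted p = 0.0953). Without miR-27 Tg replicate 3 the NK call (median 0.94, adjusted p = 0.0571) and the TGF-beta call (-0.0702, adjusted p = 0.546) were lost, the latter also without WT replicate 1. The erythroid call was lost without WT replicate 1 or 3 or miR-27 Tg replicate 2 (adjusted p = 0.300) or 3.

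**Figure D3:**
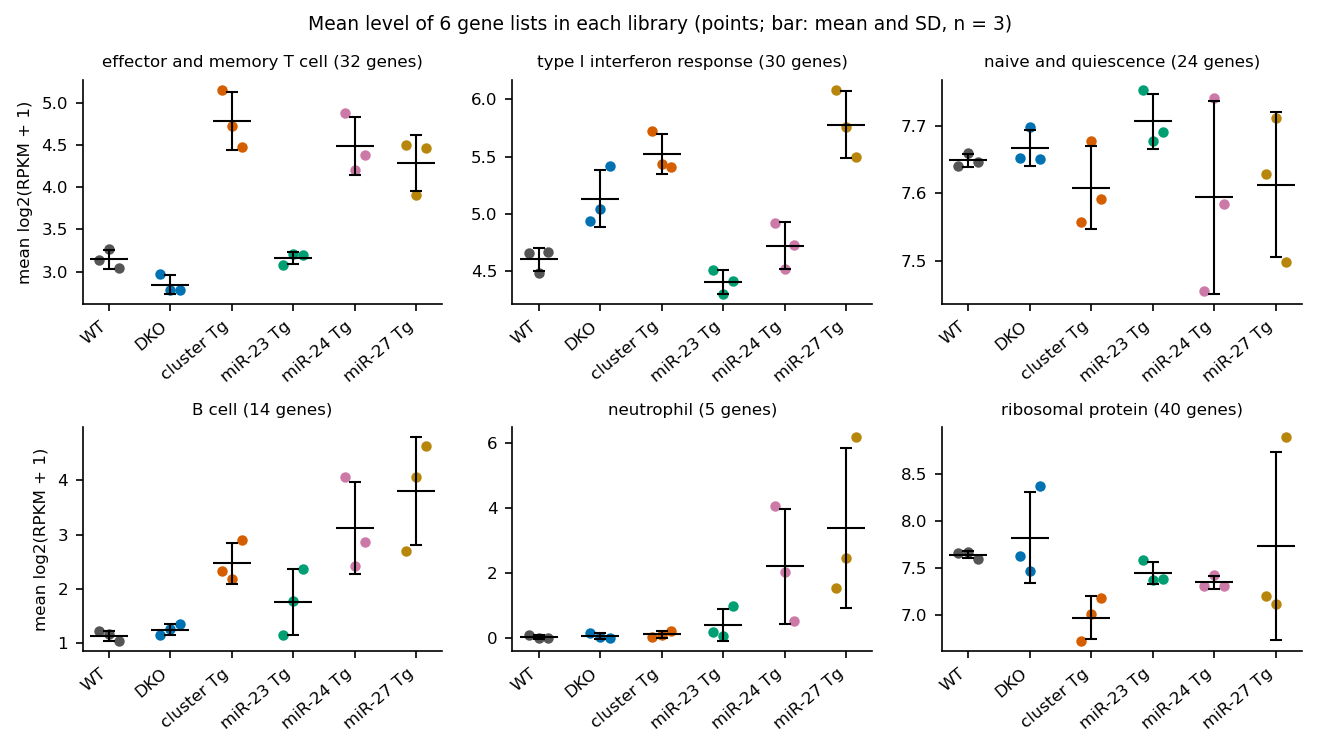
Mean log2(RPKM + 1) of 6 gene lists in each library (points), with the mean and SD of n = 3 per genotype. Effector and memory genes lie above WT in all cluster Tg, miR-24 Tg and miR-27 Tg libraries, interferon genes in all cluster Tg, miR-27 Tg and DKO libraries, and B cell genes in all cluster Tg, miR-24 Tg and miR-27 Tg libraries, while the ribosomal protein list sets DKO replicate 3 and miR-27 Tg replicate 3 apart.

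Over-expression of miR-23 alone gave 5 calls against WT. The epithelial adhesion molecule Epcam rose from 0.947 ± 0.0685 to 4.11 ± 0.229 RPKM (log2 1.39, SE 0.14, adjusted p = 0.000765). The calcium-binding Rcn1 (5.52 ± 0.138 against 11.2 ± 1.18), the zinc finger gene Zfp386 (8.68 ± 0.906 against 14.01 ± 0.426), the proapoptotic Bid (8.20 ± 0.567 against 12.5 ± 0.748) and 8430419L09Rik (7.66 ± 0.678 against 13.1 ± 0.734) fell, with adjusted p of 0.0400, 0.0400, 0.0375 and 0.0375. The last was singled out after its values were seen, since the naming rule passes over such symbols. Limma called these 5 genes, 1 higher and 4 lower, against 847 at an unadjusted p under 0.05. Camera called 4 lists, none with a member passing limma or adjusted over the list alone: B cell genes higher (median 0.54, adjusted p = 0.00795), and interferon (median -0.18, adjusted p = 0.0219), ribosomal protein (-0.22, adjusted p = 0.0336) and cholesterol genes (-0.16, adjusted p = 0.0336) lower. With an estimated correlation the adjusted p = 0.985 for each, and the ribosomal call was lost under quantile normalisation and the B cell call without the 2 libraries that stood apart. The B cell call was also lost without miR-23 Tg column 4 (median 0.27, adjusted p = 0.259), and the median was 0.82 without replicate 1. The interferon call was lost without column 3, column 4 or WT replicate 1 or 3, the ribosomal one without column 3, column 4 or WT replicate 1 or 2, and the cholesterol one without column 3, column 4 or WT replicate 2, with adjusted p up to 0.130, 0.133 and 0.681, the last without WT replicate 2, at a median of -0.0797. The effector list was not called, at a median of 0.0954. Epcam was the single gene called when any 1 of the 6 WT and miR-23 Tg libraries was left out, and quantile normalisation, with 2 calls, both higher, ended those of all 4 genes that fell (adjusted p = 0.0940, 0.0593 and 0.0655 for Rcn1, Zfp386 and Bid). Without the 2 libraries that stood apart 432 genes were called.

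Loss of both clusters was compared with WT to ask what the microRNAs hold down in unmanipulated cells. No gene passed: limma called 0 of 11099, with 81 at an unadjusted p under 0.05. That is a smaller share than the 0.05 that unchanged groups would give, and 255 lay under it without the 2 libraries that stood apart. The spread shared by all comparisons was thus likely too wide for this one. The 0 calls do not show that nothing changed. The 5 genes with the smallest p were Dhx58, an RNA sensor (20.4 ± 3.57 against 13.9 ± 2.03 RPKM), Ifit1 (26.6 ± 9.63 against 14.1 ± 2.59), Ifit3 (21.8 ± 12.3 against 9.04 ± 2.39), Cd1d2 (2.23 ± 0.473 against 0.779 ± 0.466) and the kinase Dclk2 (4.99 ± 2.02 against 2.27 ± 0.0926), each with an adjusted p of 1.00. As a group, the 30 interferon genes had a median of 0.56, none called over all genes and 5 higher adjusted over the list alone. The camera adjusted p = 5.82e-35, and it held with an estimated correlation (adjusted p = 0.0289), while fry, which does not set the list against other genes, gave an adjusted p of 0.241. Without DKO replicate 3 and miR-27 Tg replicate 3 the median was 0.32, with an adjusted p = 0.259 with an estimated correlation. The call at the preset correlation held with each of the 6 libraries left out, at medians from 0.32, without DKO replicate 3, to 0.68. Mx2 (7.16 ± 1.34 against 3.59 ± 0.966) and Irf7 (116.5 ± 29.4 against 72.8 ± 10.8) were among its members.

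Several T cell lists had a negative median in DKO and a positive one in cluster Tg. Camera called lower, with 0 members passing limma, the cell cycle (median -0.21, adjusted p = 2.10e-11; Mki67 at 1.02 ± 0.323 against 2.95 ± 2.15), effector and memory (-0.16, adjusted p = 2.80e-07; Cd44 at 6.73 ± 1.41 against 10.7 ± 1.79) and Treg lists (-0.20, adjusted p = 0.000837). It also called lower the cholesterol (-0.13, adjusted p = 0.00371), miR-24 target (-0.0633, adjusted p = 0.0234) and Th2 lists (-0.14, adjusted p = 0.0494). With an estimated correlation these gave an adjusted p of 0.228, 0.311, 0.228, 0.497, 0.228 and 0.815. Ribosomal protein genes were called higher (median 0.19, adjusted p = 0.00523, adjusted p = 0.819 with an estimated correlation), and called lower, at -0.11, without the 2 libraries that stood apart, where the miR-24 target and Th2 calls were also lost. Of these 7 calls only the effector one held with each of the 6 libraries left out in turn. Without WT replicate 2 the cell cycle call (median -0.0554, adjusted p = 0.0901) and the cholesterol call (a median of -2.16e-05, adjusted p = 0.889) were lost. The miR-24 target call was lost without WT replicate 2 (median -0.0347, adjusted p = 0.586) or DKO replicate 1 or 2, and the Treg call without DKO replicate 2 (adjusted p = 0.0502). The Th2 call held in 1 of 6 fits, the one without DKO replicate 2, and the median was 0.0124 without DKO replicate 3 (adjusted p = 0.759). The ribosomal call was lost without WT replicate 3, and the median was -0.11 without DKO replicate 3 (adjusted p = 0.137). Without DKO replicate 2 the medians of the miR-24 target, Th2 and ribosomal lists were -0.13, -0.28 and 0.38, and without WT replicate 1 that of the cholesterol list was -0.20. Medians also moved by over 1.5 times without DKO replicate 2 or 3 for the cholesterol list, WT replicate 1 or 3 for the miR-24 targets and DKO replicate 1 for the ribosomal list. In a fit of the 6 libraries alone 4 genes were called, and 2 without the 2 libraries.

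Cluster Tg and DKO, gain and loss of the same microRNAs, were also compared with each other. Genes named here were chosen after their values were seen, apart from the locus. S100a4 stood at 152.7 ± 66.8 RPKM in cluster Tg and 3.25 ± 2.07 in DKO, and Anxa2 at 69.1 ± 13.5 and 5.33 ± 1.05. Gzmk stood at 14.5 ± 5.64 and 0.147 ± 0.143, Nrp1 at 30.5 ± 9.98 and 1.13 ± 0.463, and the adhesion receptor Cd44 at 21.6 ± 2.76 and 6.73 ± 1.41. Limma called 1259 genes, 793 higher and 466 lower in cluster Tg (665 and 744 with quantile normalisation). Of the effector list, 23 were higher and 1 lower (27 and 1 adjusted over the list alone; camera adjusted p = 1.17e-20). Of the 17 Treg genes 8 were higher, Foxp3 among them (4.78 ± 0.252 against 1.604 ± 0.486; 11 adjusted over the list alone; camera adjusted p = 1.11e-07). Both held with an estimated correlation, at an adjusted p = 0.0446. Cell cycle genes had 15 of 32 higher (21 higher and 2 lower adjusted over the list alone), with the proliferation marker Mki67 at 7.07 ± 1.24 against 1.02 ± 0.323 and the topoisomerase Top2a at 9.55 ± 2.01 against 2.61 ± 0.262 (camera adjusted p = 4.02e-07, adjusted p = 0.320 with an estimated correlation). Tfh genes had 8 of 14 higher (11 adjusted over the list alone; camera adjusted p = 1.29e-07, adjusted p = 0.0883 with an estimated correlation). Of 30 interferon genes, 2 were higher, Oas1a and Lgals3bp (4 adjusted over the list alone; median 0.39; camera adjusted p = 0.00190, adjusted p = 0.573 with an estimated correlation). Of 40 ribosomal protein genes 4 were lower, among them Rps20, Rps16 and Rps3 (8 adjusted over the list alone; camera adjusted p = 5.14e-09, adjusted p = 0.547 with an estimated correlation). No B cell marker was called (11 adjusted over the list alone; camera adjusted p = 6.75e-05, adjusted p = 0.547 with an estimated correlation). Of 14 Th1 genes 7 were higher and 1 lower (9 and 2 adjusted over the list alone; camera adjusted p = 2.64e-05, adjusted p = 0.121 with an estimated correlation), and of 11 Th17 genes 4 were higher (4 adjusted over the list alone; camera adjusted p = 0.00520, adjusted p = 0.463 with an estimated correlation). The heat stress list had 1 of 15 lower (1 adjusted over the list alone; camera adjusted p = 0.0139, adjusted p = 0.573 with an estimated correlation), a list call lost without DKO replicate 3 (adjusted p = 0.0523). Markers of other cells moved in the same libraries. Of 7 CD8 markers 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.00594, adjusted p = 0.300 with an estimated correlation). Of 6 thymocyte genes 4 were higher (4 adjusted over the list alone; camera adjusted p = 6.75e-05, adjusted p = 0.0883 with an estimated correlation). Of 6 myeloid markers 2 were higher (2 adjusted over the list alone; camera adjusted p = 0.0407, adjusted p = 0.309 with an estimated correlation), a list call lost without cluster Tg replicate 1 (adjusted p = 0.0806) or DKO replicate 2 or 3. Quantile normalisation ended the heat stress and myeloid calls, and these and the Th17 call were lost without the 2 libraries that stood apart. Leaving out cluster Tg replicate 1 or DKO replicate 1 moved the 1259 calls to 561 or 814, and they were 3068 without the 2 libraries that stood apart.

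The single transgenics were compared with the whole cluster through the sum of their changes. Limma called 1 of 11099 genes as different from the sum, with 534 at an unadjusted p under 0.05. It was the hairpin Mirlet7a-1, named after its values were seen, which was listed at 0 in all 9 libraries of WT, DKO and miR-23 Tg and was 82.6 ± 51.6 RPKM in cluster Tg, 68.0 ± 23.3 in miR-24 Tg and 72.4 ± 22.8 in miR-27 Tg (adjusted p = 0.00639). B cell genes lay below the sum, with 0 of 14 called, all 14 lower adjusted over the list alone, and a median of -3.63 (camera adjusted p = 4.71e-27, adjusted p = 0.0835 with an estimated correlation). The effector list also lay below the sum, at a median of -0.73 with none called (camera adjusted p = 8.43e-06, adjusted p = 0.495 with an estimated correlation). So did the NK (median -1.68), neutrophil (-4.73), myeloid (-2.67), erythroid (-4.75) and Treg lists (-0.32), with 4, 3, 3, 0 and 1 members lower adjusted over the list alone. Their camera adjusted p were 2.24e-07, 7.75e-07, 0.00164, 0.0164 and 0.0346, and with an estimated correlation the adjusted p were 0.0835, 0.202, 0.106, 0.497 and 0.497. With each of 15 libraries left out in turn, the erythroid call held in 11 fits and the Treg call in 6 (adjusted p = 0.171 and 0.128 at the highest, without miR-27 Tg replicates 2 and 1), and the other 5 in all 15. The erythroid median was -2.35 without miR-27 Tg replicate 3, and that of the Treg list was -0.57 without miR-27 Tg replicate 2 and also moved by over 1.5 times without miR-27 Tg replicate 3 or cluster Tg replicate 1. Both calls were lost without the 2 libraries that stood apart, and that of the Treg list with quantile normalisation. The F test over the 6 genotypes called 2105 genes, 3809 when miR-27 Tg replicate 3 was left out and 5648 without both libraries that stood apart.

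Calls were shared between transgenics more often than independent lists would share them. Cluster Tg and miR-27 Tg shared 305 higher and 104 lower genes, against 36.0 and 10.1 for independent lists. Cluster Tg and miR-24 Tg shared 180 and 71, against 14.5 and 3.99, and miR-24 Tg and miR-27 Tg shared 113 and 19, against 14.9 and 4.45. Of the 4 genes that fell in miR-23 Tg, 3 fell in cluster Tg, Rcn1, Bid and 8430419L09Rik, against 0.114. Simulated unchanged groups set against the same WT libraries shared 0 in 20 simulations, which follows from the near absence of calls in unchanged groups and gives no measure of the excess. Part of the excess may come from the shared controls. Across genes, the covariance of fold changes was 0.246 for cluster Tg with miR-24 Tg (r = 0.665) and 0.240 with miR-27 Tg (r = 0.514). It was 0.194 for miR-24 Tg with miR-27 Tg (r = 0.481). For cluster Tg it was 0.115 with miR-23 Tg (r = 0.376) and 0.0610 with DKO (r = 0.222). Simulated unchanged groups with shared controls gave 0.109 (r = 0.502). They were drawn at the spread pooled over all libraries, those that stood apart included. The SD of log2 ratios was 0.291 to 0.336 between WT libraries. For miR-27 Tg replicate 3 against its genotype it was 1.12 and 1.145. The value of 0.109 is thus likely too high for these WT libraries. Whether cluster Tg shares more with miR-23 Tg or DKO than the controls give cannot be decided from it. Genes are not independent replicates.

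Genes with a matching site in the 3′ UTR lay lower in each transgenic. Genes with a miR-24 site (1944 of 10233) were shifted by a log2 of -0.0893 (SE 0.0093) in miR-24 Tg and -0.0878 (SE 0.0113) in cluster Tg, and none of 15410 other words was as low in either. Genes with a miR-27 site (1743) were shifted by -0.0961 (SE 0.0132) in miR-27 Tg, where 1 other word was as low, and by -0.0648 (SE 0.0117) in cluster Tg, where 6 were. Genes with a miR-23 site (1665) were shifted by -0.0322 (SE 0.0070) in miR-23 Tg and -0.0699 (SE 0.0121) in cluster Tg, where 8 and 4 words were as low. In cluster Tg the 4 were the miR-24 word and parts of the 8-base sites (a site followed by A) of the 3 families. In miR-23 Tg the lowest words (GAGAAAC, GAAACCC, AGAGATC, GCCATCT and CTAGAGA) were not parts of the miR-23 site. The highest word there, ATTTTGT, had a t of 8.18, against -4.60 for the miR-23 word. All 6 shifts passed (adjusted p = 0.000292 to 0.000876). The shift of miR-23 in its own transgenic turned to 0.0094 (adjusted p = 0.194) when the regression had no terms for UTR length and GC share. Without these terms the shift of miR-27 was -0.214 in miR-27 Tg and -0.0307 in cluster Tg, and that of miR-23 in cluster Tg was -0.0261 (-0.106 with 8-base sites). In DKO the shifts were -0.0110 for miR-23, -0.0045 for miR-24 and -0.0036 for miR-27, where a higher rank among the words was tested, and none passed (adjusted p = 0.840, 0.517 and 0.499). With no terms for UTR length and GC share they were -0.0641, -0.0495 and -0.0531, and none passed. Without DKO replicate 3 those of miR-23 and miR-27 turned to 0.0103 and 0.0097 and passed (adjusted p = 0.0171 and 0.0174). That of miR-24 stayed at -0.0041 there and did not pass (adjusted p = 0.914). With 8-base sites and all libraries kept, the miR-24 shift was 0.0132 and passed (adjusted p = 0.0025). Library by library, site genes lay below those of WT in 3 of 3 libraries in each of these 6 comparisons with transgenics, with mean differences from -0.0260 to -0.110 and an exact permutation p = 0.1, the smallest possible with 3 against 3. In DKO the differences were -0.0084, 0.0025 and -0.0002 (exact p = 0.8, 0.8 and 1). This measure was not specific to the family over-expressed. Genes with a miR-24 site also lay below every WT library in miR-23 Tg (highest -0.0045, lowest WT 0.00064). Those with a miR-23 site did so in miR-27 Tg (highest -0.0016, lowest WT 0.00078). In miR-24 Tg, genes with a miR-23 or miR-27 site lay above every WT library. The miR-24 sites in miR-27 Tg and the miR-27 sites in miR-23 Tg overlapped with WT.

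**Figure D4:**
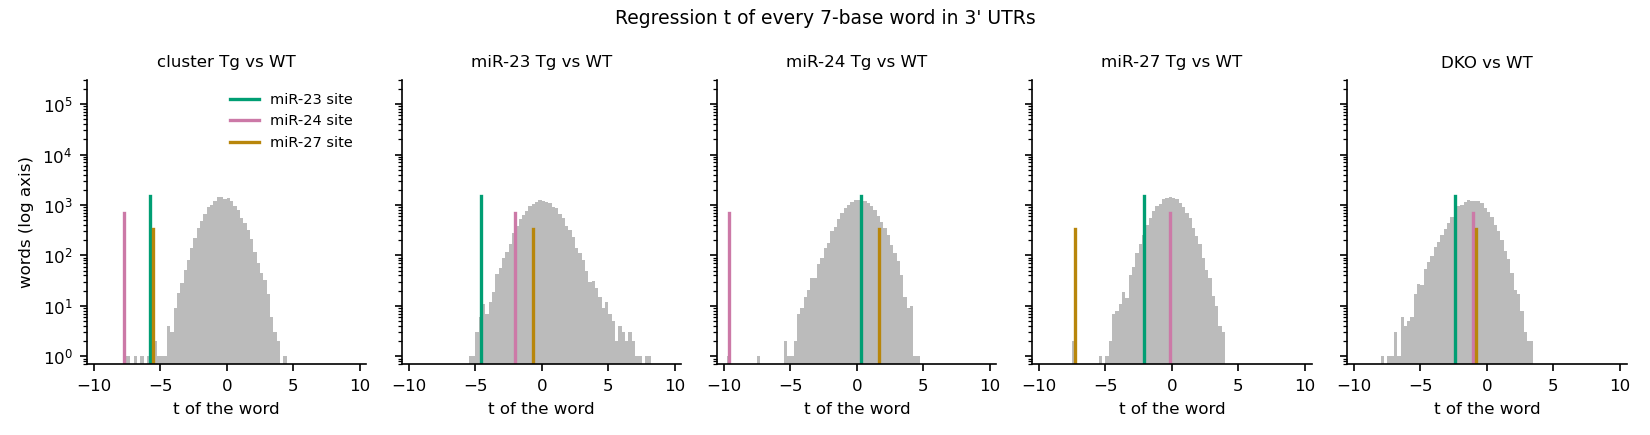
Distribution of regression t values over all 7-base words found in 3′ UTRs, for each genotype against WT, with the words matching miR-23, miR-24 and miR-27 as coloured lines (vertical axis: number of words, log scale). The miR-24 word is the lowest of 15411 in miR-24 Tg and cluster Tg, and the miR-27 word ranks 2 in miR-27 Tg.

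**Figure D5:**
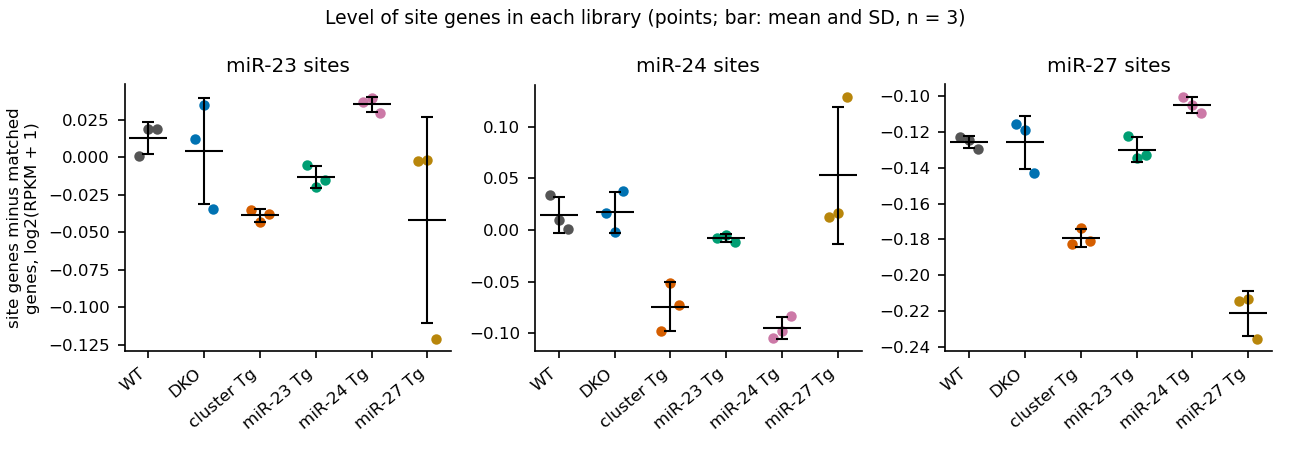
Mean log2(RPKM + 1) of genes with a site minus length-matched genes without one, in each library (points), with the mean and SD of n = 3 per genotype, for each family. In cluster Tg and in the transgenic of the same family all 3 libraries lie below the 3 WT libraries. The same holds for miR-24 sites in miR-23 Tg and for miR-23 sites in miR-27 Tg.

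The share with a site among called genes that fell was counted without a separate test and without terms for UTR length and GC share. In the regression without these terms, 121 other words were as low as the miR-27 word in miR-27 Tg. Part of the shares below may therefore come from UTR length or GC share. In miR-24 Tg 52 of 134 (38.8%) had a miR-24 site, against 19.0% of all genes searched, and in miR-27 Tg 112 of 334 (33.5%) had a miR-27 site, against 17.0%. In cluster Tg 58 of 301 (19.3%) had a miR-23 site, against 16.3% of all genes searched, 85 (28.2%) a miR-24 site and 84 (27.9%) a miR-27 site. The genes with a site and the largest falls in miR-24 Tg were Igfbp4, Slc16a5, Ttyh3, the membrane skeleton protein Epb4.1l1 (0.595 ± 0.180 against 3.86 ± 0.471 RPKM) and Cd81. The first 4 also fell in cluster Tg, whereas Cd81 had a log2 of -0.52 there (adjusted p = 0.443). In miR-27 Tg they were Rgs1 (13.5 ± 8.06 against 42.7 ± 10.1), the microtubule-binding Hook1 and Eml5, Lrrc75b and the GTPase Rab20, and in cluster Tg none of these 5 was called (adjusted p = 0.0770 to 0.841). In miR-23 Tg, Rcn1, Zfp386 and 8430419L09Rik have a site and Bid has none. Zfp386 had a log2 of -0.0069 in cluster Tg (adjusted p = 0.992).

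Few literature targets of the 3 microRNAs were called in their transgenics. Of 11 measured miR-23 targets none was called in miR-23 Tg. Ppif, a mitochondrial pore regulator, was 20.5 ± 2.02 against 27.5 ± 1.43 there (log2 -0.41, adjusted p = 0.599) and fell in cluster Tg (11.2 ± 1.96, adjusted p = 0.000621) and in miR-27 Tg (11.3 ± 3.76, adjusted p = 0.000751). In miR-27 Tg this was the only call in the miR-23 list, which camera placed lower (1 adjusted over the list alone; adjusted p = 0.0229, adjusted p = 0.353 with an estimated correlation, and not called without the 2 libraries that stood apart, or without miR-27 Tg replicate 3 alone, at a median of 0.0353). Of 17 miR-24 targets, the kinase Mapk14 fell in miR-24 Tg (65.6 ± 0.724 against 83.0 ± 4.45, adjusted p = 0.0479, lost under quantile normalisation). It also fell in cluster Tg (55.9 ± 3.52, adjusted p = 0.00103) and in miR-27 Tg, while Ifng, the Th1 cytokine, rose in miR-24 Tg and cluster Tg (6.36 ± 4.11 and 5.43 ± 3.27 against 0.617 ± 0.130). The naive-cell factor Tcf7 was 506.0 ± 54.4 in miR-24 Tg against 920.3 ± 54.2 in WT (log2 -0.87, adjusted p = 0.0505), and H2afx was 10.04 ± 2.03 against 23.7 ± 1.89 (adjusted p = 0.0505). Of 13 miR-27 targets, Smad2 fell in miR-27 Tg and the nuclear receptor Rxra rose (6.80 ± 0.695 against 4.19 ± 0.541, adjusted p = 0.00416), as it did in cluster Tg with Bcl6. Gata3, the Th2 regulator, was 40.01 ± 10.49 in miR-27 Tg against 26.3 ± 3.52 (adjusted p = 0.158), and Rel was 10.1 ± 7.52 against 21.3 ± 4.98 (log2 -1.40, adjusted p = 0.248). In DKO none of the 41 targets measured was called.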

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

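The fits without miR-27 Tg replicate 3 and DKO replicate 3, with library weights and without Mir, Snord and Snora genes, median-ratio scaling for named genes and lists, and list tests that leave out 1 library, were chosen only after the results were seen. Unless said otherwise, the cause of a change was not tested. The counts of calls for cluster Tg, miR-24 Tg and miR-27 Tg vs WT, cluster Tg vs DKO and the F test stayed within 1.5 times the reported value with a pseudocount of 0.1, no filter, no variance trend, quantile or median-ratio scaling and without Mir, Snord and Snora genes. Without the 2 libraries, the calls were 3225 for cluster Tg, 2 for DKO, 432 for miR-23 Tg, 1937 for miR-24 Tg and 2218 for miR-27 Tg vs WT, 3068 for cluster Tg vs DKO, 4 for the sum and 5648 for the F test. With library weights fitted gene by gene they were 3399, 3, 1400, 2451, 3065, 4290, 201 and 7559 in the same order; a restricted likelihood estimate of the weights stopped before it converged and is not used. Fits of only the 6 libraries compared gave 2302 calls for cluster Tg, 4 for DKO, 14 for miR-23 Tg, 851 for miR-24 Tg and 43 for miR-27 Tg, 41 of them shared with the 993. For miR-23 Tg there were 2 calls with quantile normalisation and 1 without Mir, Snord and Snora genes. For the sum there were 2 with a pseudocount of 0.1, 2 without a filter, 2 with quantile normalisation and 0 without those genes, which leave out its single call. Leaving out 1 library of the genotypes compared at a time gave 419 to 710 calls for cluster Tg, 0 for DKO, 1 for miR-23 Tg, 180 to 303 for miR-24 Tg, 533 to 1223 for miR-27 Tg, 561 to 901 for cluster Tg vs DKO, 0 to 3 for the sum and 1575 to 3809 for the F test. Camera made 66 list calls without those of the sum, and 3 with an estimated correlation.

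Shifts of site genes kept their sign in the transgenics, except that of miR-23 in miR-23 Tg, which was 0.00944 with no terms for UTR length and GC share. In DKO the shifts with no such terms were -0.0641 for miR-23, -0.0495 for miR-24 and -0.0531 for miR-27, and none passed. In the transgenics without these terms sizes moved by over 1.5 times for miR-27 in miR-27 Tg (-0.214) and cluster Tg (-0.0307) and for miR-23 in cluster Tg (-0.0261), and with 8-base sites for miR-23 in cluster Tg (-0.106). In DKO the miR-24 shift was 0.0132 with 8-base sites and passed. Leaving out 1 library there gave -0.0241 to 0.0103 for miR-23 and -0.0111 to 0.00969 for miR-27. Both passed without DKO replicate 3, where the miR-24 shift was -0.0041 and did not pass. Without the 2 libraries the ribosomal protein list changed sign in DKO (-0.11), miR-27 Tg (-0.52) and the sum (0.28), and so did Phb in miR-27 Tg (-0.45). Over single libraries left out, 1359 list results kept their side of the threshold, 63 lost their call and 53 gained one. In 4 the camera direction turned round, with a call in the main fit or the new one. More medians than these changed sign. That of the Th2 list in DKO was 0.0124 without DKO replicate 3, and that of the miR-23 targets in miR-27 Tg was 0.0353 without miR-27 Tg replicate 3. The ribosomal median ran from -0.1081 to 0.3811 in DKO, from -0.5165 to 0.4403 in miR-27 Tg and from -0.604 to 0.2836 in the sum, and that of the cell cycle list in miR-23 Tg from -0.1441 to 0.1535. Of the named gene results, 404 kept their side of the threshold with quantile normalisation, 21 lost their call and 14 gained one. With a pseudocount of 0.1 these were 425, 4 and 10, and over all single libraries left out 2305, 313 and 16. Only relative depth is known, 0.634 to 1.47 times that of WT replicate 1, so no detection limit could be given.

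Libraries with the same replicate number deviated together somewhat more than others did. Of 30 same-numbered pairs 11 had a correlation of deviations over 0.1 (median 0.0806, and -0.0382 for pairs with other numbers). The highest, 0.580, joined DKO replicate 3 and miR-27 Tg replicate 3, and the lowest was -0.111. Of 15 libraries, 8 correlated best with their own number. An effect shared by replicates of 1 number thus stays open, and the main fit has no term for it. With the replicate block the calls were 837 for cluster Tg, 0 for DKO, 331 for miR-24 Tg, 852 for miR-27 Tg, 1091 for cluster Tg vs DKO and 1654 for the F test, and 60 list calls. Of the named gene results 373 kept their side of the threshold with the block, 26 lost their call and 4 gained one, and of list results 143 kept it and 2 lost their call. The block leaves the fold changes, and so the site shifts, as they were (-0.0699 for miR-23, -0.0878 for miR-24 and -0.0648 for miR-27 in cluster Tg). No paired analysis was possible for miR-23 Tg and the sum because 2 miR-23 Tg libraries carry no number.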

Other observations

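The comparisons between transgenics, the words of other families, the grouping of genotypes, the genes named other than Gt(ROSA)26Sor, and the tests of explanations and splits were chosen only after results were seen. Cluster Tg differed from miR-24 Tg by 246 genes (145 higher and 101 lower, limma), from miR-27 Tg by 421 (220 and 201) and from miR-23 Tg by 1147 (726 and 421). The miR-27 Tg and miR-24 Tg libraries differed by 1441 (753 higher and 688 lower in miR-27 Tg). Single genes that were lower in cluster Tg than in miR-24 Tg included the NK receptor Klrd1 at a log2 of -2.02 (adjusted p = 0.000584), the death ligand Fasl at -1.22 (adjusted p = 0.00120) and the pore-forming Prf1 at -1.23 (adjusted p = 0.0166). The receptor kinase Axl (1.89, adjusted p = 0.000803) and the secreted Angptl2 (2.00, adjusted p = 3.84e-05) were higher. Against miR-27 Tg, cluster Tg had higher Ccr9 (2.73, adjusted p = 0.00119), Il18r1 (1.99, adjusted p = 0.00351) and Ly6c2 (1.74, adjusted p = 0.0156), and lower Igj (-3.15, adjusted p = 0.0103) and S100a9 (-5.01, adjusted p = 0.0280). Between miR-27 Tg and miR-24 Tg, the interferon-induced Oas2 was higher in miR-27 Tg (2.29, adjusted p = 4.36e-05), and Ccr9 (-3.51, adjusted p = 2.51e-05) and Prf1 (-2.75, adjusted p = 1.77e-05) were lower.

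Words of a family other than the one over-expressed were ranked from the lowest of 15411. The miR-24 word ranked 766 in miR-23 Tg (-0.0135) and 7699 in miR-27 Tg (-0.0017), the miR-23 word 8388 in miR-24 Tg (0.0032) and 594 in miR-27 Tg (-0.0287), and the miR-27 word 4354 in miR-23 Tg (-0.0046) and 13710 in miR-24 Tg (0.0159). Gt(ROSA)26Sor was 17.1 ± 3.23 RPKM in WT, 22.7 ± 7.83 in DKO, 6.24 ± 1.4 in cluster Tg, 5.3 ± 0.0331 in miR-23 Tg and 6.83 ± 2.11 in miR-24 Tg (n = 3 each). In miR-27 Tg (n = 3) it ranged from 4.96 to 20.7, with the highest value in replicate 3. It was called between cluster Tg and DKO (log2 -1.68, adjusted p = 0.0146, limma) and in no comparison with WT (adjusted p = 0.0550 in cluster Tg). The globin gene Hbb-bh1 was listed at 0 in all 6 WT and DKO libraries and lay between 0.855 and 8.98 in all 12 transgenic ones, with limma calls in miR-24 Tg (adjusted p = 0.0192) and miR-27 Tg (adjusted p = 0.00776) but not in cluster Tg (0.0547) or miR-23 Tg (adjusted p = 0.125). When the 6 genotypes were put into 2 groups of 3, WT, DKO and miR-23 Tg against cluster Tg, miR-24 Tg and miR-27 Tg separated 264 genes without overlap (209 higher and 55 lower in the latter), Mirlet7a-1 among them. The other 9 groupings separated 0 to 72. If all 18 libraries were exchangeable, 0.00411% of genes, or 0.457 genes, would be separated. The 3 libraries of a genotype move together in these groupings, so that value gives no measure of how unusual the 264 are. Whether the 2 sets of genotypes were prepared as separate batches is not given in the sources used here, so a difference in preparation stays open beside the genotype for the calls of cluster Tg, miR-24 Tg and miR-27 Tg vs WT and for what they share.

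In miR-27 Tg replicate 3 and DKO replicate 3, levels relative to WT were lower for longer transcripts, with rank correlations over 11006 genes of -0.299 and -0.342, where the lowest of the other 16 libraries had -0.0661. For DKO replicate 3 low depth is argued against by its relative depth, 1.22 times that of WT replicate 1. In miR-27 Tg replicate 3 the relative depth was 0.634, the lowest of all libraries, so low depth stays open there. A wrong label of the whole of miR-27 Tg replicate 3 is argued against by its Mir27a level of 27980.5 RPKM. That level lay below the 216755 and 234933 of the other miR-27 Tg libraries. Its Gt(ROSA)26Sor was 20.7, against 5.36 and 4.96 in those libraries and 14.1 to 20.5 in WT. DKO replicate 3 also had the highest Gt(ROSA)26Sor of its genotype, at 30.9. Whether replicate 3 of miR-27 Tg held only cells of its genotype was not tested. The length trend is consistent with a difference in RNA quality or library preparation, which may account for these libraries standing apart, and no biological explanation was tested.

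Of 32 effector and memory genes, 22, 14 and 15 rose in cluster Tg, miR-24 Tg and miR-27 Tg, and 1, 0 and 2 fell (camera adjusted p = 0.0763, 0.0577 and 0.247 with an estimated correlation). B cells, which a sort for CD4 would remove, are argued against as their whole cause in cluster Tg, though not excluded. There 24 of 32 effector genes lay higher than in miR-27 Tg (median 0.44), 5 of them called and 0 called lower. None of the 14 B cell markers lay higher (median -1.33), but 0 were called lower. The miR-27 Tg libraries include replicate 3, which stood apart, and falls of effector genes through miR-27 itself were not separated from this difference. In miR-24 Tg, 9 B cell markers were called, with Cd74 at 123.5 ± 92.7 RPKM, and B cells and the transgene cannot be told apart there or in miR-27 Tg, since both rose in the same libraries. CD8 T cells also stay open, although the sort was for CD4, with 3 CD8 markers called higher in cluster Tg (Cd8a at 7.17 ± 3.98 RPKM) and Ctsw lower. A change of the naive cells by the microRNAs is a hypothesis that these data leave open beside memory cells, which the gate for a naive surface phenotype would remove at least in part, other cells within the sort, and a separate preparation of these genotypes.

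Of 30 interferon genes, 17 rose in cluster Tg and 22 in miR-27 Tg (camera adjusted p = 0.1 and 0.161 with an estimated correlation), and camera called the list higher in DKO, where no gene passed. B cells are argued against as the source, since the interferon median was 0.13 in miR-24 Tg, where that of B cell markers was 1.86. In DKO the median was 0.56 (camera adjusted p = 0.0289 with an estimated correlation), and 0.32 without the 2 libraries that stand apart (adjusted p = 0.259), so these libraries may hold part of it. The list was higher with gain and with loss of the cluster, and an effect of the genotypes was not separated from differences between the mice or their housing, which are not given in the sources used here.

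The splits of 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. The real split gave 941 calls for cluster Tg, 5 for miR-23 Tg, 398 for miR-24 Tg, 993 for miR-27 Tg and 1259 for cluster Tg vs DKO, where the highest of the others gave 1 each and only 1 of 10, the real one, reached the count. For DKO vs WT the real split gave 0 by limma (81 at an unadjusted p under 0.05) and the highest other 1, so 10 of 10 were as large. For the F test 1 of 100 splits, the real one, reached 2105 (highest other 195), the lowest share that 100 splits can give. This does not tell the genotype from a preparation shared by its libraries, which is not given in the sources used here. For the sum 38 of 100 splits gave at least the 1 call of the real one, so that call is no more than other splits give. These splits mix genotypes that differ from each other, so they cannot decide whether the call is due to chance. The highest split gave 210, which points to a structure of the samples whose source was not tested.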
